A study of Mus musculus with 8 samples.

How the data were processed

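The measurements came from mouse CD4 T cells of the C57BL/6 strain, with ribosome-depleted RNA sequenced in 8 libraries, 2 in each of 4 groups. The groups, per the labels, were untreated naive cells, Th17 cells cultured for 72 h, wild-type Th17 cells and DDX5-deficient Th17 cells of a further 72 h culture. The medium held anti-CD3 at 0.25 µg/mL, anti-CD28 at 1 µg/mL, TGF-β at 0.1 ng/mL and IL-6 at 20 ng/mL, per the labels' treatment fields, whereas the growth protocol there gives TGF-β as 0.1-5.0 ng/mL and the treatment protocol gives 48 and 72 h. The submitters' processing notes name STAR 2.6.1a, featureCounts, DESeq2 1.18.1 and the mm10 build, and the labels name SAILOR, a caller of A-to-I editing from RNA reads, with a confidence of 0.99. The settings of the read counting, its use of strand, the removal of known variants and the SAILOR version are not stated there.

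The table of naive and Th17 cells gave counts per gene and library, called original per the file headers. It also gave a normalized signal per library, which equalled the original count divided by a single size factor per library made by the authors, and its mean over the 4 libraries. The log2 fold change of Th17 over naive cells, its standard error, the Wald score and the p-value and adjusted p-value in that table were made by the authors with DESeq2, per the file headers and the submitters' processing notes. The sign of the log2 fold change followed the normalized means in 7774 of the 7774 genes that the authors' adjusted p called. The table listed 16308 genes, of which 16295 were matched by identifier to the GENCODE M21 annotation of the same build, 16270 of them protein coding, and 25 symbols that had turned into dates were restored from that annotation. Long noncoding RNAs such as Malat1 and Neat1 were not analysed here.

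The editing tables gave for each site and library the fraction of edited reads, on a scale of 0 to 1 as the deposited values show, and it was printed as a percent. They also gave a confidence score per call, per the file headers, and a coverage count. The deposited coverage was that of library 2 of the Th17 cells and of library 2 of the wild-type cells, since fraction times coverage was whole within 0.01 at 100% of the sites there and at 6.52% to 7.92% of the sites in the other libraries. Coverage, strand and score were given only at sites listed for Th17 cells in the naive and Th17 table, and the depth behind the other levels is unknown. The strand of sites listed for naive cells alone was taken from the annotated gene, which gave the strand of the file at 98.4% of the 369 sites where both were known. The site table of naive and Th17 cells listed a site for a group only when it had a level in both libraries of that group. The other editing table listed only sites with a score of at least 0.990 in both wild-type libraries, with no such limit in the DDX5-deficient libraries. Site positions were taken as deposited and located in GENCODE M21.

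Reads on genes were 20426728 and 16154625 in the naive libraries and 26624436 and 11768994 in the Th17 libraries, and 3 reads per library corresponded on TMM-scaled library sizes to a group mean of 0.185 CPM, counts scaled to a common library size, in naive and 0.166 CPM in Th17 cells. A fold against a group with 0 reads was computed against 3 reads in each library and is a lower bound, and with 1 to 3 reads the ratio of summed reads is given with its exact conditional binomial 95% interval. Intervals of shares are exact Clopper-Pearson intervals at 95%, and intervals of medians rest on binomial order statistics. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

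Expression was tested with edgeR 4.0.16 in R 4.3.3 on the original counts, with filterByExpr, TMM normalization, robust quasi-likelihood fits on group alone and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Group values are means of CPM on TMM-scaled library sizes with SD over n = 2 libraries. Tested on simulated counts with 200 changed genes, the fit recovered 45% of 100 genes changed by a log2 of 1 and 83% of 100 changed by a log2 of 2. It made 18 false calls among 12455 genes tested. Set against the 45 and 83 correct calls, the share of false calls exceeded the threshold of 0.05 in this simulation. In the data 7800 of 11989 tested genes were called, a far larger share than was changed in the simulation. The adjustment depends on that share, so neither the recovery nor the share of false calls carries over to the data. The 19 gene lists were fixed before the data were examined, and the 17 with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted over the lists. They cover the Th17 programme, naive and quiescence genes, T cell activation, cell cycle, glycolysis, cholesterol synthesis, ribosome biogenesis, interferon-stimulated genes, editing enzymes and partners, long noncoding RNAs, the TGF-β and STAT3 response, and markers of Th1, Th2 and Treg states and of B, myeloid, CD8 and NK, dendritic and erythroid cells.

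Genes were named by a rule also fixed then. It took the 10 largest rises and the 10 largest falls in log2 fold change among called genes with a mean normalized count of at least 100 and an established symbol. It added the called members of each list with the 2 largest and the 2 smallest absolute changes, and always a set of genes that held Il17a, Il17f, Adar, Adarb1, Ddx5, Ddx17, Malat1 and Neat1. Some genes that the rule takes are not reported here. For sites it took the genes with the 10 largest site numbers per table and, since no coverage per group was at hand, the 5 largest differences in each direction among sites listed in all libraries of both groups. Other genes and sites in the text were chosen after their values were seen.

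Site counts and overlaps used exact positions. Levels were compared at sites with a value in all 4 libraries of a table and coverage of at least 10 reads in the library that has it, by a two-sided exact sign test on the differences of group means, adjusted over 2 tests. Sites are not independent replicates. A Fisher test per site was left out because edited and total reads of the other libraries were not at hand. Edited genes were set against the expression calls by Fisher's exact test, two-sided, among genes expressed at least as highly as the least expressed edited gene. Computations outside R used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6, and plots matplotlib 3.10.9.

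Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, a minimum mean normalized count of 10, no filter, an adjusted p under 0.01, an absolute log2 fold change of at least 1, readjusted deposited p-values, recentred folds, a block on the replicate number and each library left out. For the lists they were a preset correlation of 0.05, an estimated correlation, the log2 fold change as statistic, a background of genes with a mean normalized count of at least 10, and 10000 random lists matched on expression. With an estimated correlation camera rests on the residual degrees of freedom, few at 2 libraries per group, so it has little power. For sites they were a score of 0.999, coverage of 5 and 20, calls in both libraries, a window of 50 bases, genes in place of sites, and leaving out the gene with the most sites or sites at a level of 0.95 or more. The deposited DESeq2 calls, the plus strand alone, a coverage minimum of 50 for levels, and a score of 0.99 in every library were added after the data had been seen. Left-out libraries and the replicate block for levels, and a two-sided Cochran-Mantel-Haenszel test of edited genes in 10 strata of expression in the cells whose sites are counted, were added then too. So was coverage of 10 for the site counts, which were otherwise left without a minimum because coverage is given for a single library.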

Results

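The series profiled RNA from mouse naive CD4 T cells and from Th17 cells, the interleukin-17 producing helper cells that arise from them in culture with TGF-β and IL-6. Gene expression was read in 2 naive and 2 Th17 libraries, with 13080 and 12499 genes with at least 1 read in the naive and 14435 and 15316 in the Th17 libraries. Reads on genes ran from 11768994 to 26624436 per library. A-to-I edited sites were listed for the same 4 libraries and for 2 wild-type and 2 DDX5-deficient Th17 libraries. Such sites are adenosines that ADAR enzymes turn into inosine, which is read as guanosine, and DDX5 is an RNA helicase. Log2 CPM, read counts scaled to a common library size, correlated across genes at r = 0.993 between the naive libraries and 0.969 between the Th17 libraries, and at 0.761 to 0.782 between groups. Genes are not independent replicates in these correlations.

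Th17 cells compared with naive cells expressed the cytokine genes that define the lineage at levels far above counting error. Il17a (chromosome 1, 20730905 to 20734496) had 0 reads in naive cells and 1083 ± 225 CPM (SD, n = 2) in Th17 cells, at least 5846-fold higher. Il17f had 1 naive read against 2037 ± 45.5 CPM (SD, n = 2), a ratio of 66917 with a counting interval of 12010 to 2643120. The adjusted p was 1.8e-07 for Il17a and 1.1e-07 for Il17f by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Klf2, which encodes a transcription factor of quiescent T cells, fell from 322 ± 16.1 to 1.33 ± 0.173 CPM (SD, n = 2).

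Of 11989 genes tested by edgeR's quasi-likelihood test, 4116 were higher and 3684 lower in Th17 cells at an adjusted p under 0.05, and 2971 and 2158 of them by a log2 of at least 1. Without naive library 1 the calls were 2436 higher and 2567 lower, and without naive library 2 they were 2380 and 2738. The lone naive library is then assumed to vary like the Th17 libraries. Genes with near-identical copies, among them the Ifi200 and Ly6 families, and genes that overlap on opposite strands may share reads, because the use of strand in counting is not stated.

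The other genes with the largest rises had no read in naive cells. Il22, a cytokine of Th17 cells, reached 395 ± 137 CPM (SD, n = 2), at least 2132-fold higher. The uridine phosphorylase gene Upp1 was at least 1398-fold higher, the proteoglycan gene Lum at least 1242-fold and the stearoyl-CoA desaturase gene Scd1 at least 944-fold. The lower bounds were 693-fold for the cytokine gene Il24, 578-fold for Dclk1, 547-fold for the retinoic acid binding protein gene Crabp2 and 435-fold for Ermn. These 8 genes had adjusted p from 1.3e-07 to 0.038 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Il24 lay at 181 and 75.8 CPM in the Th17 libraries and was not called without the filter on low counts.

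Among the largest falls, the interferon-inducible genes Ifi208 and Ifi213 changed by a log2 of -9.91 (SE 0.44) and -9.02 (SE 0.29), and Ifit1bl1 by -9.35 (SE 0.36). Rasgrp2, a Rap1 activator in lymphocyte adhesion, fell from 589 ± 17.9 to 2.03 ± 0.562 CPM (SD, n = 2). Falls of similar size were found for the nucleoside transporter gene Slc28a2b at -9.69 (SE 0.39), the ADP-ribosyltransferase gene Art2b at -9.23 (SE 0.29), the VIP receptor gene Vipr1 at -8.63 (SE 0.33) and the T cell surface gene Cd7 at -8.16 (SE 0.30). The urea transporter gene Slc14a1 had 3 Th17 reads, a ratio of 0.00168 (0.000345 to 0.00491). Cnga1 had 2 Th17 reads, a ratio of 0.00368 (0.000445 to 0.0134). Slc14a1 was not called without either naive library.

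The Th17 programme rose as a group. Of its 22 tested members 21 rose and 0 fell, and 21 rose adjusted over the list alone. Beside Il17a and Il22, Nfkbiz rose by a log2 of 1.41 (SE 0.21) and Stat3, which carries the IL-6 signal, by 0.95 (SE 0.17). Il9, with 0 naive reads and 14.1 ± 13.8 CPM in Th17 cells (SD, n = 2), did not pass at an adjusted p of 0.094 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and was named after its values were seen. The list had an adjusted p of 8.3e-26 by camera and an adjusted p of 0.19 with an estimated correlation. Nfkbiz was not called without naive library 2.

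Genes of naive and quiescent T cells fell. Of 20 tested members 17 fell and 0 rose, and adjusted over the list alone 17 fell and 1 rose. Klf2 changed by a log2 of -7.87 (SE 0.22), the surface antigen gene Ly6c1 by -4.56 (SE 0.52), Foxp1 by -0.97 (SE 0.16) and Ccr7, the receptor that guides T cells to lymph nodes, by -0.55 (SE 0.17). The 3 members that did not pass, named after their values were seen, were Bach2 at 0.53, Satb1 at -0.05 and Tob1 at 0.12 in log2, and Bach2 was the member called higher over the list alone. The list had an adjusted p of 2.3e-11 by camera and an adjusted p of 0.19 with an estimated correlation. Ccr7 was not called when either Th17 library was left out.

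T cell activation genes rose in 16 of 18 tested members, also adjusted over the list alone, and 0 fell. The IL-2 receptor gene Il2ra rose from 2.63 ± 0.266 to 2840 ± 545 CPM (SD, n = 2) and the inhibitory receptor gene Ctla4 by a log2 of 8.50 (SE 0.32). The amino acid transporter genes Slc7a5 and Slc3a2 rose by 1.26 (SE 0.18) and 0.89 (SE 0.18). Cd69 at 0.24 and Egr2 at 0.97 in log2, both named after their values were seen, did not pass. The adjusted p was 2.0e-19 by camera, and the adjusted p with an estimated correlation was 0.43. Slc3a2 was not called without naive library 1.

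Cell cycle genes rose in 23 of 24 tested members, also adjusted over the list alone, and 0 fell. The mitotic genes Ccnb1 and Aurkb rose by a log2 of 6.25 (SE 0.33) and 6.21 (SE 0.32), and the replicative helicase genes Mcm7 and Mcm4 by 0.61 (SE 0.16) and 0.56 (SE 0.16). Mcm2, named after its values were seen, lay at 108 ± 6.95 CPM in naive and 91.0 ± 21.3 in Th17 cells (SD, n = 2) and did not pass. The list had an adjusted p of 1.3e-15 by camera and an adjusted p of 0.45 with an estimated correlation. Mcm4 and Mcm7 were not called without Th17 library 1 or without either naive library.

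Glycolysis genes rose in 14 of 14 tested members, also adjusted over the list alone. Hexokinase gene Hk2 rose from 0.441 ± 0.126 to 341 ± 33.6 CPM (SD, n = 2) and the lactate exporter gene Slc16a3 from 2.67 ± 0.196 to 427 ± 53.0. Hk1 rose by a log2 of 1.38 (SE 0.17) and Gpi1 by 0.56 (SE 0.20). The adjusted p was 6.0e-14 by camera, and the adjusted p with an estimated correlation was 0.45. Gpi1 was not called without either naive library, without Th17 library 1, with the replicate block, with no filter or with a minimum mean normalized count of 10.

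Cholesterol synthesis genes rose in 15 of 19 tested members and 1 fell, and adjusted over the list alone 16 rose and 1 fell. Idi1 and the sterol demethylase gene Cyp51 rose by a log2 of 3.21 (SE 0.17) and 2.61 (SE 0.16) and Nsdhl by 0.79 (SE 0.19), whereas Dhcr7, of the last step to cholesterol, fell by 0.55 (SE 0.16). Mvk at 0.18 and Sc5d at 0.24 in log2, both named after their values were seen, did not pass over all genes. The list had an adjusted p of 3.4e-06 by camera, an adjusted p of 0.28 with an estimated correlation and one of 0.30 with the log2 fold change as the statistic. Without naive library 1 neither Nsdhl nor Dhcr7 was called, and without Th17 library 2 Dhcr7 was not.

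Ribosome biogenesis genes were not called as a group against the other genes. Of 20 tested members 7 rose and 0 fell, and 4 rose adjusted over the list alone. Nop2 rose by a log2 of 0.86 (SE 0.19), the nucleolar gene Npm1 by 0.79 (SE 0.24), Nop56 by 0.50 (SE 0.17) and Rrp12 by 0.48 (SE 0.17). By camera the adjusted p was 0.92, and it was 0.96 with an estimated correlation. These 4 genes were not called when either naive library was left out, nor were Npm1, Nop56 and Rrp12 without Th17 library 1 or with a minimum mean normalized count of 10, nor Nop56 and Rrp12 with no filter.

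Interferon-stimulated genes went both ways. Of 19 tested members 5 rose and 7 fell, and adjusted over the list alone 6 rose and 7 fell. Ifit3, Oasl2 and Oas1a changed by a log2 of -2.29 (SE 0.36), -2.13 (SE 0.20) and -0.72 (SE 0.26). Bst2 rose by 0.70 (SE 0.18), and Isg15, Ifi44, Ifih1 and Eif2ak2, named after their values were seen, rose by 1.65, 1.33, 0.84 and 1.58. The adjusted p was 0.37 by camera and 0.87 with an estimated correlation. Bst2 was not called without Th17 library 1 or either naive library, and Oas1a was not called in 8 of 12 alternatives.

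Among genes of RNA editing, the enzyme genes moved in opposite directions. Adar, which encodes the widely expressed deaminase ADAR1, fell from 305 ± 65.0 to 134 ± 9.52 CPM (SD, n = 2), a log2 fold change of -1.18 (SE 0.19) with an adjusted p of 5.8e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adarb1, which encodes ADAR2, rose from 1.32 ± 0.0794 to 215 ± 35.8 CPM (SD, n = 2), by a log2 of 7.33 (SE 0.24). The helicase genes Ddx5 and Ddx17 changed by a log2 of -1.18 (SE 0.21) and -0.76 (SE 0.17), with Ddx5 at 2684 ± 425 CPM in naive and 1183 ± 104 in Th17 cells (SD, n = 2). Of 17 tested members of the list of editing enzymes and partners 4 rose and 8 fell, also adjusted over the list alone. The other 3 that rose were Stau2 by 4.25 (SE 0.48) and, named after their values were seen, Aimp2 by 1.01 and Zfr by 0.49, while Stau1 changed by -0.39 (SE 0.15). The adjusted p was 0.92 by camera, toward lower, and 0.96 with an estimated correlation, and the median log2 fold change of the list was -0.35 whereas its mean was 0.33. Stau1 was not called when either Th17 library or naive library 1 was left out, with the replicate block or with no filter.

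Genes of the TGF-β and STAT3 response were also split, with 4 of 14 tested members higher and 5 lower, the same counts adjusted over the list alone. Ltbp3 rose by a log2 of 4.73 (SE 0.70), Pim1 by 1.19 (SE 0.16), Bcl3 by 0.87 (SE 0.16) and Junb by 2.14. Il6st, the shared signalling subunit of IL-6 family receptors, changed by -3.42 (SE 0.26), the IL-6 receptor gene Il6ra by -3.31, and the TGF-β pathway genes Smad7, Smad3 and Ski by -2.35, -1.23 and -1.64. Junb, Il6ra, Smad7, Smad3 and Ski were named after their values were seen. By camera the adjusted p was 0.20, and it was 0.50 with an estimated correlation. Ltbp3, at 3.19 and 8.26 CPM in the Th17 libraries, was not called when either naive library was left out.

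Some markers of other T helper states rose beside the Th17 genes, while others fell or did not pass. Of 8 tested Th1 markers 6 rose and 2 fell, also adjusted over the list alone. The IL-12 receptor gene Il12rb2 rose by a log2 of 10.49 (SE 0.32), the granzyme gene Gzmb by 6.81 (SE 0.55) and Stat4 by 0.87 (SE 0.16), whereas Il18r1 and, named after its values were seen, Eomes changed by -2.29 (SE 0.16) and -2.44. The Th1 list had an adjusted p of 0.0025 by camera and an adjusted p of 0.45 with an estimated correlation. Of 6 tested Th2 markers 3 rose and 0 fell, also adjusted over the list alone. These were Il24, the chemokine receptor gene Ccr4 by 8.20 (SE 0.35), and Il4 with 0 naive reads and 3.20 ± 2.92 CPM in Th17 cells (SD, n = 2), at least 17.3-fold higher. Th17 library 1 lay above library 2 for these genes, with Il4 at 5.27 and 1.14, Il24 at 181 and 75.8 and Ccr4 at 254 and 160 CPM, as it did for Il13 at 257 and 23.4 and Gata3 at 81.6 and 28.6. Gata3, Il13 and Il1rl1, named after their values were seen, did not pass, and Gata3, the Th2 transcription factor, lay at 53.7 ± 5.53 and 55.1 ± 37.4 CPM (SD, n = 2). The Th2 list had an adjusted p of 0.011 by camera and an adjusted p of 0.52 with an estimated correlation. Il4 was not called when either naive library was left out.

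Treg markers rose in 6 and fell in 2 of 9 tested members, also adjusted over the list alone. The integrin gene Itgb8 rose by a log2 of 6.90 (SE 0.53), Nrp1 by 2.34 (SE 0.35) and Ikzf4 by 0.85 (SE 0.19), and Lrrc32 with 3 naive reads had a ratio of 87.0 (29.5 to 424). Th17 library 2 lay above library 1 for Itgb8 at 23.9 and 13.5, Nrp1 at 20.4 and 12.6 and Lrrc32 at 11.2 and 6.38 CPM. For Ikzf4 library 2 lay below library 1, at 31.6 and 32.9 CPM. Foxp3, which encodes the transcription factor of regulatory T cells, fell by 6.07 and Gpr83 by 2.79, both named after their values were seen. The list had an adjusted p of 0.10 by camera and an adjusted p of 0.50 with an estimated correlation. Nrp1 and Ikzf4 were not called without naive library 2.

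Markers of cells other than CD4 T cells summed to low levels in both groups, except where stated. The 8 measured B cell markers summed to 2.83 CPM in naive and 1.01 in Th17 cells, and of the 2 tested Cd79a changed by a log2 of -2.32 (SE 0.75), also adjusted over the list alone, a call lost in 8 of 12 alternatives. Too few B cell markers were tested for a set test. The 11 measured myeloid markers summed to 13.4 and 8.91 CPM, and of 7 tested 1 rose and 4 fell, also adjusted over the list alone. Cd14 had 1 naive read and a ratio of 101 (17.9 to 4038), Itgam had 3 Th17 reads and a ratio of 0.0369 (0.00741 to 0.113), Fcer1g and Fcgr3 changed by -3.20 (SE 0.76) and -2.72 (SE 0.61), and Lyz2, named after its values were seen, by -3.82. Without either naive library Itgam, Fcer1g and Fcgr3 were not called, and Fcer1g was not called in 6 of 12 alternatives in all. The myeloid adjusted p was 0.45 by camera and 0.59 with an estimated correlation.

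The 9 measured CD8 and NK markers summed to 100 CPM in naive and 54.3 in Th17 cells. Of 6 tested 1 rose and 3 fell, also adjusted over the list alone, with the perforin gene Prf1 at -3.46 (SE 0.19), Klrd1 at -1.54 (SE 0.34), Cd8b1 at -0.78 (SE 0.20) and Nkg7 at 2.38 (SE 0.20) in log2. Klrd1 and Cd8b1 were not called without naive library 2. Of 4 tested dendritic cell markers 2 rose and 1 fell, also adjusted over the list alone. The MHC class II gene H2-Ab1 rose from 3.05 ± 0.934 to 81.7 ± 2.81 CPM (SD, n = 2), Zbtb46 rose by 3.70 (SE 0.59) and Itgax changed by -3.63 (SE 0.92), the latter pair not called without either naive library and Itgax not called in 6 of 12 alternatives in all. Of 4 tested erythroid markers Epor alone was called, with 3 naive reads and a ratio of 50.1 (16.9 to 245), also adjusted over the list alone. The median log2 fold change of the erythroid list was -1.48, its mean 0.12 and its test pointed lower. Adjusted p by camera was 0.45 for CD8 and NK, 0.27 for dendritic and 0.92 for erythroid markers, and with an estimated correlation 0.59, 0.59 and 0.96. Of the 16 long noncoding RNAs listed, 0 were measured, and 0 sites were listed in Malat1 or Neat1.

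**Figure D1:**
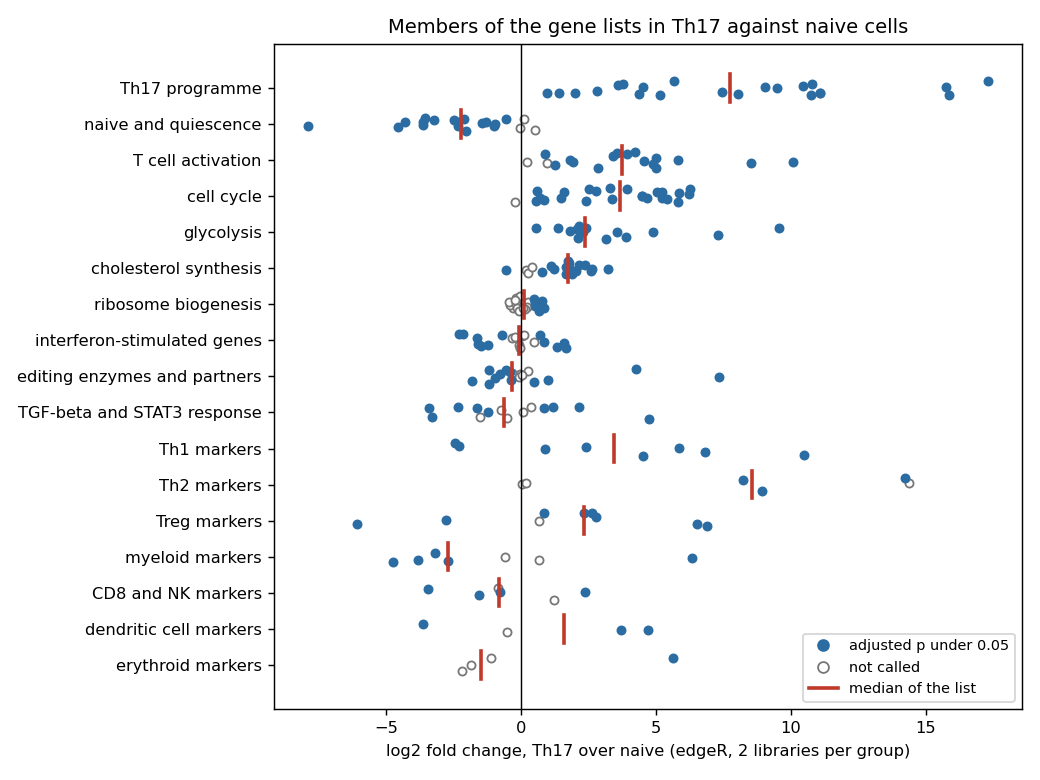
Each point is a tested list member, placed by its log2 fold change of Th17 over naive cells on the x axis, with lists down the y axis. Filled points have an adjusted p under 0.05 by edgeR and red bars mark list medians. Fitted folds of genes with 0 to 3 reads in a group depend on the prior count. All 14 glycolysis genes lie right of 0, and 17 of the 20 naive and quiescence genes are called left of it.

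The site tables asked which adenosines are edited in naive and in Th17 cells. Naive cells had 571 listed sites in 270 genes and Th17 cells 399 sites in 131 genes, with 101 sites listed for both. The genes with the most sites in naive cells were the Schlafen gene Slfn5 with 25, Wdr76 with 16, the DNA damage mediator gene Mdc1 with 13 and Tox4 with 13, followed by Cds2, Dffa and Mapk1ip1l with 11 each and Abhd2, Padi2 and Sfxn2 with 9 each. In Th17 cells they were Rpa1, of the single-stranded DNA binding complex, with 24 sites, Wdr76 with 21, the spindle checkpoint gene Mad2l1 with 17, Slfn5 with 14 and Rnf168 with 10, followed by Ankrd28 with 9, Ccr4 and Slc35e2 with 8 each and Fnbp1 with 7. The genes named for naive cells all lie on the plus strand. Rpa1, Ankrd28, Ccr4 and Fnbp1 lie on the minus strand, where only 16 naive sites were listed. Their place in the Th17 ranking alone is therefore no sign that their editing was gained in Th17 cells. The sites of Slfn5 in naive cells lay between 82962104 and 82963686 of chromosome 11 and those of Rpa1 in Th17 cells between 75300545 and 75301040 of chromosome 11, in the mm10 build and within annotated 3′ UTRs.

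Most sites lay in 3′ UTRs, 83.9% of the naive and 85.0% of the Th17 sites. The base in the transcript was A at 99.5% of the 431 naive-only, 100% of the 97 shared and 100% of the 257 Th17-only sites in annotated exons. A guanosine preceded the site at 3.96%, 4.12% and 3.50% of them, against 25.7% of all adenosines of these transcripts (two-sided exact binomial p = 1.2e-33, 3.2e-08 and 1.0e-21). A low share of G at that position is a known preference of ADAR enzymes.

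Sites of naive cells lay nearly all on the plus strand. They were 528 on the plus strand, 16 on the minus strand and 27 with no or ambiguous strand, so that 97.1% of those with a strand lay on the plus strand (exact Clopper-Pearson 95% interval 95.3% to 98.3%). Th17 cells had 204 sites on the plus and 195 on the minus strand, 51.1% plus (46.1% to 56.1%). Of the plus-strand Th17 sites 98 (48.0%, 41.0% to 55.1%) were also listed for naive cells, and of the minus-strand ones 3 (1.54%, 0.318% to 4.43%), a difference with p = 3.5e-31 by Fisher's exact test, two-sided. The test and the intervals count each site as independent. The Th17 sites lie in 131 genes, and strand goes with the gene, so the precision is overstated. Counts of sites in the 2 cell types therefore stand beside the plus-strand counts of 528 and 204, a view chosen after the data were seen. Site numbers also depend on depth and on expression of the gene, and a site had to be listed in both libraries. Reads on genes were 20426728 and 16154625 in the naive and 26624436 and 11768994 in the Th17 libraries. The counts are thus no measure of how much editing each cell type had.

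**Figure D2:**
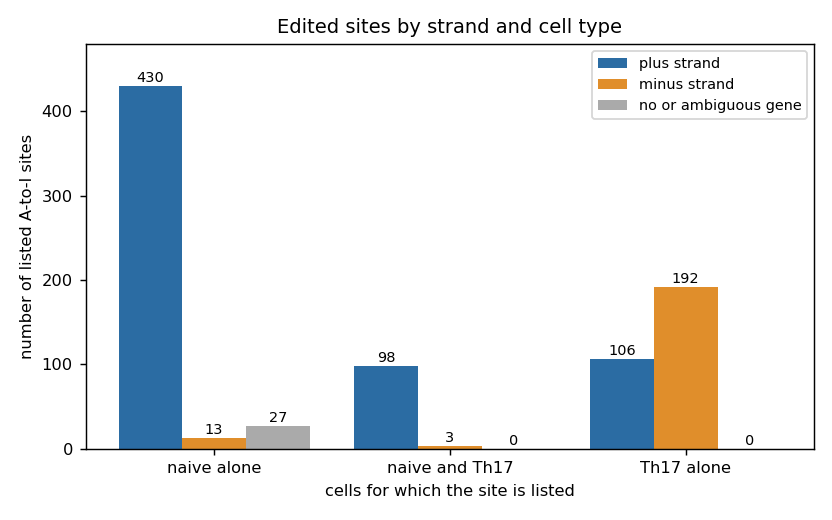
Bars give the number of listed A-to-I sites (y axis) for sites listed in naive cells alone, in both cell types and in Th17 cells alone, by strand. Sites of naive cells alone number 430 on the plus and 13 on the minus strand, and those of Th17 cells alone 106 and 192.

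At sites that both cell types shared, the level of editing was lower in Th17 cells. At 83 shared sites with coverage of at least 10 reads in Th17 library 2, the median level was 34.6% and 32.4% in the naive and 19.6% and 20.0% in the Th17 libraries. It was lower in Th17 cells at 62 sites and higher at 21, a median difference of -8.27 percentage points (95% interval -13.6 to -6.02) with p = 7.5e-06 by a two-sided exact sign test and 1.5e-05 adjusted over 2 tests. At 42 sites both Th17 libraries lay below both naive libraries and at 9 above, in sum 61.4% of the sites against 33.3% by chance. At the 28 sites with coverage of at least 50, a minimum chosen after the data were seen, the median difference was -18.6 points. Over all listed sites, which differ between the cell types, the medians were 15.7% and 19.0% in naive and 25% and 28.6% in Th17 cells.

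The largest fall of level was at position 108337130 of chromosome 9 in the 3′ UTR of Rhoa, a small GTPase gene, from 73.3% and 81.3% in the naive to 21.9% and 15.6% in the Th17 libraries, with coverage of 424 in the last. Falls from 63.1% and 71.5% to 13.1% and 10.3% in Phc2 (128752175 of chromosome 4) and from 45.9% and 52.7% to 6.98% and 6.16% in Ywhag (135909342 of chromosome 5) followed the same course. Sites in Atl3 and Pum2 changed by -46.0 and -43.9 points, with Th17 libraries at 28.4% and 8.57% and at 40.5% and 12%. The largest rise was in Mdc1 (35858620 of chromosome 17), from 21.6% and 20.0% to 57.1% and 53.8% at coverage of 13. Rises of 25, 24.2 and 19.5 points were found at an intergenic site (32224957 of chromosome X, coverage of 6), in Cds2 and in Klhl24, and at the fifth, of 15.5 points in Wdr76, the groups overlapped. Of the 10 genes with at least 3 shared sites at coverage of at least 10, 5 of 5 sites of Mapk1ip1l, 4 of 4 of Tapbp and 3 of 3 of Tox4 were lower in Th17 cells and 3 of 3 of Mdc1 higher. The other 6, Slfn5, Wdr76, Cds2, Malt1, Padi2 and Xrn1, were mixed, with 5 sites higher and 9 lower in Slfn5 and 3 higher and 4 lower in Wdr76.

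**Figure D3:**
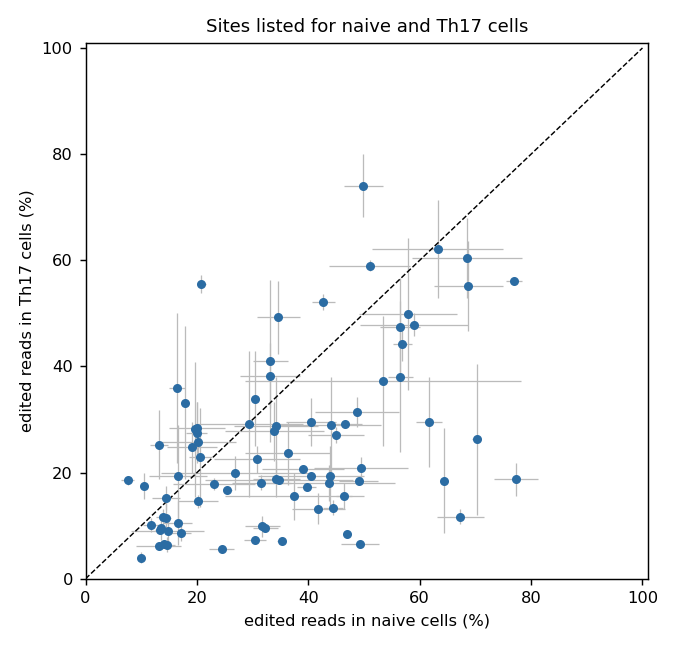
Each point is a site with coverage of at least 10, its mean percent of edited reads in 2 naive libraries on the x axis and in 2 Th17 libraries on the y axis, with lines spanning the 2 libraries. The dashed line marks equal levels, and 62 of the 83 sites lie below it.

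The comparison of wild-type with DDX5-deficient Th17 cells asked whether editing depends on the helicase DDX5. Expression of Ddx5 itself in these libraries was not analysed here. The table held 355 sites in 143 genes, all selected on the wild-type libraries, so that sites edited in DDX5-deficient cells alone are outside it. Rpa1 had 28 sites, Ccr4 15, Gnl3l and Wdr76 11 each, Mad2l1 and Prrg4 9 each, Rbbp4 and Rnf168 8 each and Ankrd28 and Cd48 7 each, and 81.1% of the sites lay in 3′ UTRs. In DDX5-deficient cells 277 sites (78.0%) were called with a score of at least 0.99 in both libraries, 49 in a single library and 29 in neither. Sites lacking a value in a DDX5-deficient library had median coverage of 7 in wild-type library 2, against 19 for the 328 sites with values in both.

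Among sites with a value in all 4 libraries, the level of editing did not shift in 1 direction in DDX5-deficient cells. A site without a value in a DDX5-deficient library is outside this comparison, as is a site not called in wild-type cells. At 256 sites with coverage of at least 10 in wild-type library 2 the median level was 17.1% and 20.0% in wild-type and 21.2% and 20.4% in DDX5-deficient libraries, with 126 sites higher and 130 lower. The median difference was -0.201 points (95% interval -1.42 to 0.965), with p = 0.85 by a two-sided exact sign test and 0.85 adjusted over 2 tests. Without wild-type library 1 the median difference was -2.06 points (exact sign test p = 0.015), and without wild-type library 2 it was 1.90 (exact sign test p = 0.0071), so the sign followed the library kept. Within a group, wild-type library 2 lay 2.94 points above library 1 and DDX5-deficient library 2 lay 1.90 points below library 1 (medians; exact sign test p = 9.5e-06 and 2.4e-04).

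Single sites differed between the genotypes in both directions. At 63 sites both DDX5-deficient libraries lay above both wild-type libraries and at 54 below, in sum 45.7% of the sites against 33.3% by chance. The 2 other ways of pairing the libraries gave 22.7% and 27.3%. A site with 4 different values separates exactly 1 of the 3 ways, so these shares are no second yardstick. The largest fall was at position 74226650 of chromosome X in Flna, from 92.3% and 83.3% in wild-type to 57.7% and 31.3% in DDX5-deficient libraries. Falls of 41.2, 40.7 and 40.0 points were found in Nt5dc3, Mfap1a and at adjacent sites 45377141 and 45377142 of chromosome 4 in Dcaf10. Coverage at these 5 sites was 5 to 7 reads. The largest rise was at 134589292 of chromosome X in the 3′ UTR of Gla, the α-galactosidase A gene, from 25% and 15.4% to 50% and 71.4% at coverage of 13. Sites in Bri3bp and Wdr76 rose by 27.0 and 23.4 points, and at sites in Filip1l and Lactb2 the groups overlapped, with Filip1l at 98.6% and 16.9% in the wild-type libraries. Of 26 genes with at least 3 sites at coverage of at least 10, 19 were mixed, among them Rpa1 with 16 sites higher and 12 lower. In the other 7 the sites went 1 way, and of these, chosen after the values were seen, the histone chaperone gene Rbbp4 had 8 of 8 sites higher and Mad2l1 6 of 6 lower in DDX5-deficient cells. The Rbbp4 sites lay between 129309878 and 129310001 of chromosome 4, so they may share reads and are not separate observations. Some of the 7 genes had only 3 sites. With 2 libraries against 2, no single site can reach p under 0.05 by an exact permutation test, whose smallest two-sided p is 0.333.

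**Figure D4:**
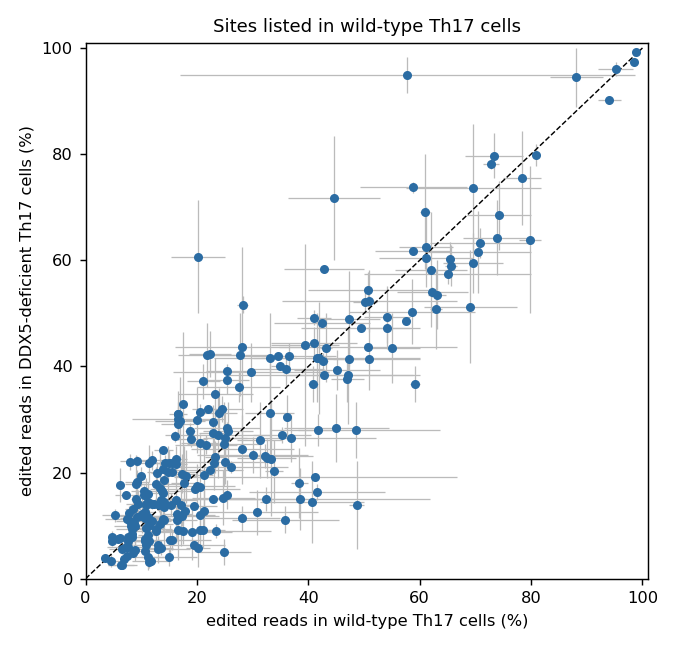
Each point is a site with coverage of at least 10, its mean percent of edited reads in 2 wild-type Th17 libraries on the x axis and in 2 DDX5-deficient libraries on the y axis, with lines spanning the 2 libraries. The dashed line marks equal levels, with 126 sites above and 130 below it.

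Both experiments listed Th17 sites. Of the 355 sites of wild-type Th17 cells 207 (58.3%) were also listed for the Th17 cells of the first experiment, and across these sites the mean levels correlated at r = 0.842 and rho = 0.863, with sites that are not independent replicates.

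Edited genes were set against the expression change to ask whether they were among the genes that changed. Btg1 and Tgfbr1 carried sites listed for naive cells and not for Th17 cells in the table of the first experiment, and Hif1a and Tnfrsf9 the reverse, all chosen after their values were seen. Genes with naive sites made up 127 of 3157 genes lower in Th17 cells, an odds ratio of 1.66 (adjusted p = 4.0e-04), and 50 of 2514 genes higher in Th17 cells, an odds ratio of 0.567 (adjusted p = 7.1e-04), by two-sided Fisher's exact tests among 8678 genes, of which 263 were edited, adjusted over 6 tests. That background was limited by the mean over both cell types, while a naive site can be listed only where naive cells express the gene. In 10 strata of naive expression, a test added after the data were seen, the pooled odds ratios were 1.03 (95% interval 0.796 to 1.33) among lower and 1.11 (0.802 to 1.53) among higher genes, with adjusted p of 0.99 and 0.89 by the two-sided Cochran-Mantel-Haenszel test, so the association was not kept. Genes with Th17 sites, 130 of 10145, gave odds ratios of 1.34 among higher and 0.716 among lower genes by Fisher's exact test, neither past the threshold (adjusted p = 0.19 each).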

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

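Added after the data had been seen were the deposited DESeq2 calls, the plus strand alone, coverage of 10 for site counts and 50 for levels, levels without high sites or the gene with the most sites or below a score of 0.99, and leaving out or blocking libraries for levels, and strata of expression for edited genes. Calls numbered 6136 to 8611 under the other settings, and no called gene had the opposite sign in any. Leaving out each library in turn gave 5003 to 8519 calls, 2380 to 4847 higher and 2567 to 3672 lower, with the fewest without a naive library, for a cause that was not tested. With a log2 of at least 1 the calls were 5129, of which 2158 lower. Of 1020 values of 85 named genes, 925 kept their side of the threshold, 95 lost the call and 0 reversed, with 85 recentred values among them that keep their p. Deviations from the group means correlated across genes at -0.034 between libraries of the same replicate number, a single value that cannot settle whether samples were paired. Library 2 of naive and of Th17 cells carries the same sample code in the labels, and library 1 does not. The replicate block, which pairs both numbers, called 7738 genes. With an estimated correlation, 0 lists instead of 8 were called, at adjusted p of 0.19 for the Th17 programme and naive genes, 0.28 for cholesterol synthesis, 0.43 for activation, 0.45 for cell cycle, glycolysis and Th1 markers, and 0.52 for Th2 markers. Naive genes had an estimate of -0.0102, below the preset 0.01, yet the camera p went from 6.7e-12 to 0.017. Gene correlation therefore did not weaken that list, and the few residual degrees of freedom bear on all lists. Estimates for activation, cell cycle and glycolysis were 0.653, 0.787 and 0.776, and there both effects cannot be told apart. The log2 fold change as statistic gave cholesterol synthesis 0.30 and pointed ribosome biogenesis lower, and random lists gave myeloid markers 0.0038; the cause was not tested.

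Coverage of at least 20 left 182 Th17 sites, 58 shared sites and 150 sites called in both DDX5-deficient libraries, as a stricter limit must. Genes in place of sites numbered 270 for naive cells, 131 for Th17 cells, 52 for both and 112 for DDX5-deficient cells, and the plus strand alone held 204 Th17 sites. Sites called with 1 DDX5-deficient library left out were 295 to 308. The level difference of Th17 from naive cells ran from -10.3 to -6.71 points over the left-out libraries. That of DDX5-deficient from wild-type cells ran from -2.06 to 1.90, and with the replicate block it was 2.50 within number 1 and -2.84 within number 2, so 2 settings gave a call of the opposite sign; coverage of at least 20 gave 0.379, not called, and the cause was not tested. In strata of naive expression the odds ratios of naive-edited genes were 1.03 among lower and 1.11 among higher genes, and 1.02 and 1.20 on plus-strand genes alone, all without a call. The first background did not hold naive expression equal. The background also changed from 8678 to 8240 genes with the strata, and neither change was tested alone. Coverage of at least 5, calls in both libraries of naive and of Th17 cells and recentring could not change a count, because of how the sites were listed and because recentring leaves each p as it is. Not run were left-out libraries for naive and Th17 sites, which are listed only when in both libraries, a score limit for naive sites, which have none, a window in the DDX5 table, whose sites share positions by construction, and a pseudocount, since counts were tested.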

Other observations

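Chosen only after the result was seen were the tests on expression, thin coverage, a single library, Adar mRNA and loss of DDX5 below, and the interval bounds of the tests on the other experiment and on the splits were added after their values had been seen.

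Few listed sites lay in coding sequence, 33 in naive cells, 7 in Th17 cells and 6 in the DDX5 table, and the genes here were chosen after their values were seen. In the Th17 cells of the first experiment the coding site of Cog3, of the Golgi tethering complex (75719719 of chromosome 14), was edited at 74.0% and 57.7%. The coding site of Cyfip2, of the WAVE actin regulatory complex (46272643 of chromosome 11), was edited at 8.68% and 11.8%. Adarb1 had coding sites at 77322607 and 77322621 of chromosome 10, edited at 36.8% and 31.6% and at 24.4% and 37.5%. In the DDX5 table the Cyfip2 site lay at 22.4% and 18.0% in wild-type and 9.38% and 2.24% in DDX5-deficient libraries, and a site of the splicing gene Son (91656133 of chromosome 16) at 12% and 10.8% against 4.30% and 2.07%. In the Th17 cells of the first experiment that Son site lay at 7.98% and 6.41%. There the Cyfip2 and Son sites both lay below the wild-type libraries of the DDX5 table, so their levels also differed between the experiments. Cog3 lay at 65.9% and 56.3% against 54.9% and 70.0%.

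Several immune genes of the fixed lists carried edited sites, also chosen after their values were seen. Apobec3, a cytidine deaminase gene, had a site shared by both cell types (79907547 of chromosome 15) at 40.9% and 57.8% in naive and 22.9% and 18.9% in Th17 cells. The Th2 receptor gene Ccr4 had 8 sites in Th17 cells, the highest at 27.1% and 30.9%. Il21, a cytokine gene of Th17 cells, was edited at 6.41% and 6.19% (37224569 of chromosome 3) in Th17 cells and, in the DDX5 table, at 2.96% and 7.46% in wild-type and 10.8% and 13.1% in DDX5-deficient libraries. Sites of Hif1a on chromosome 12 went both ways in the DDX5 table, with 73947511 at 8.33% and 7.50% in wild-type and 23.5% and 20.5% in DDX5-deficient libraries, and the intronic 73928840 at 29.8% and 20.0% against 2.56% and 7.41%.

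In 4053 genes with at most 2 naive reads in all, 2460 had a read in Th17 library 1 and 3320 in Th17 library 2, with medians of 0.0376 and 0.425 CPM.

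Of the sites listed for naive cells with a known strand, 97.1% lay on the plus strand. Low expression of minus-strand genes in naive cells was argued against, since among Th17 sites in genes not called higher in Th17 cells 0.917% of 109 minus-strand and 65.2% of 112 plus-strand sites were also listed for naive cells; a first comparison, of median log2 fold changes of 0.18 and 0.34 for genes of minus-strand and plus-strand sites of Th17 cells alone, had been replaced by this one after its value was seen. A loss of most minus-strand naive calls before the table was deposited is a candidate explanation, since among sites with coverage of at least 50 the share also listed for naive cells was 3.51% of 57 on the minus strand (exact Clopper-Pearson 95% interval 0.428% to 12.1%) and 65.0% of 40 on the plus strand. The share lies under the bound of 6.50% set beforehand, 0.1 of that of the plus strand, but its interval reaches above it. That interval also counts sites of the same gene as independent. Weak editing of minus-strand transcripts in naive cells would give the same low shares, and the levels could not decide on it. Medians were 25.3% at the 16 minus-strand and 18.0% at the 528 plus-strand naive sites (two-sided permutation test, p = 0.101). Only sites that were called have a level, so editing too weak to be called lies outside that test. Strand here is only the orientation in the genome build, and Th17 cells showed no such imbalance. The plus-strand share was 51.1% in Th17 cells and 47.9% in wild-type Th17 cells of the DDX5 experiment.

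At shared sites the level was lower in Th17 than in naive cells. Chance levels at sites thinly covered in Th17 library 2 were argued against, since the median difference at the 28 sites with coverage of at least 50 there was -18.6 points (95% interval -28.1 to -7.61). The depth behind the naive levels and those of Th17 library 1 is unknown, so chance levels from thin coverage there were not tested. A single library that stands apart was argued against as the whole cause, since the highest of the 4 medians between a Th17 and a naive library was -5.60 and the highest end of their 95% intervals -3.54, against at most 1.52 between libraries of a group; the bound had first been -4, met by the medians but not by the intervals, and was replaced after these values were seen. A shift of these Th17 libraries alone stays open, with wild-type Th17 cells of the other experiment at -4.56 points from naive cells over 82 sites (95% interval -10.4 to -0.466, two-sided exact sign test p = 0.035). Lower Adar mRNA in Th17 cells, at a log2 fold change of -1.18, may play a part and cannot be told apart from the other changes between the groups, of which Adarb1 at 7.33 went the other way.

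More sites separated the DDX5-deficient from the wild-type libraries than separated the other pairs, 117 against at most 70 of 256. A site with 4 different values separates exactly 1 of the 3 splits, so more sites for the groups leave fewer for the others. Counted over sites, shifts shared by all sites of a library were argued against. With the library medians set equal 51.2% of the sites separated the groups and at most 25% the other pairs. That is a difference of 26.2 points (95% interval 15.2 to 34.4 from 5000 resamples of sites). The resamples treated sites of the same gene as independent, so the interval may be too narrow. Equal medians were not combined with 1 site per gene, so this argument was not tested over genes. A few genes with many sites were not excluded, since with 1 site per gene the shares were 45.1% and 30.4% of 102 sites, a difference of 14.7 points (-1.96 to 31.4). Loss of DDX5 may account for part of the 117 sites, since 33.3% of the 256 sites would separate the groups by chance. It cannot be told apart from other differences between these 4 libraries. Only 3 splits of 4 libraries exist, too few for a share under 0.05, with 117 sites for the groups and 70 as the highest other.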
